A study of Mus musculus with 35 samples.

How the data were processed

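RNA-seq covered 19 libraries of total mouse pancreas in 8 groups, 6 of them with 2 libraries. ATAC-seq (4 libraries), H3K27ac and H3K4me3 ChIP-seq (4 libraries per mark) and 4 input libraries came from control and Ezh2KO clones of UN-KC-6141 cells. Groups were taken from the sample titles. The labels' genotype and treatment fields read Ezh2KO for each ChIP and input library, also where the title reads control, and the titles were used. Each RNA library carries its own number, and whether each comes from its own animal is not stated beyond that number. The input libraries have no file of their own and were not used.

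The deposited RNA table holds expression per gene, an other normalized measure per the file headers and the values: it has 3 decimals, differs in total between libraries and scales with transcript length. Whether it is TPM or RPKM/FPKM is not stated. HOMER is the only tool the submitters' processing notes name, without a version, and the RNA aligner and genome build are not given in the sources used here. Of 23608 genes listed, 4212 were at 0 in every library. Read totals are not given. From the steps of low values among 1227 short genes, 1 read on a 1 kb transcript was worth 0.0439 to 0.263 units (median 0.0969, from 12 libraries with enough such values). Each of these libraries held only 4 to 28 such values, and the lowest and highest steps rest on 7 and 6, so they are rough. A value near 0.1 thus stands for about 1 read on such a transcript in a library near the median. In other libraries, and at other transcript lengths, it stands for more or less. Gapdh was listed at 0 to 1.04 in each library although it is widely expressed, so a gene at 0 is only called listed at 0, and genes with near-identical copies, such as amylases, trypsins, Ear3 and Ear12, are uncertain.

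For ChIP-seq, per the file headers, the authors counted tags with HOMER annotatePeaks.pl in 1000 bp windows around merged IDR regions of mm10, and compared genotypes with getDiffExpression.pl using the simpleNorm option. The deposited signal per library is a tag count divided by a size factor, per the file headers. The log2 fold change, p-value and adjusted p-value of each window are the authors' own, per the file headers, and the engine behind the test is not named. The tables list windows already chosen for differing, by an absolute log2 fold of at least 1 and an adjusted p under 0.05 in the values, so windows that did not differ are missing. Library totals in the headers were 5627567 to 10124468 tags for H3K27ac and 11443443 to 22085511 for H3K4me3, of which 16.2% to 27.6% and 4.28% to 7.51% lay in listed windows. The ATAC-seq regions are irreproducible discovery rate (IDR) sets, 1 per genotype, written with HOMER mergePeaks per the file headers, and their deposited score runs from 540 to 1000. That they are ATAC-seq regions follows from a directory name in the H3K27ac header. Aligners and tool versions are not given in the sources used here.

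RNA values were tested with limma 3.58.1 (trend, robust) in R 4.3.3 on log2(value + 1), with 1 mean per group over all 19 libraries so that small groups share the estimate of the spread. Genes with a value of 5 or more in at least 2 libraries were kept (10128). Fold changes are on that scale, which understates changes of low genes. P-values were adjusted by Benjamini-Hochberg over the genes kept, with a threshold of 0.05, two-sided. The design had provided for edgeR if the table held whole counts; it does not, so limma was used as the design states for normalized values. Comparisons were cerulein with control and KrasG12D with WT at each day, the mean genotype difference of the control groups over both days, day 7 with day 3 after cerulein, and the genotype by cerulein interaction. Since a few enzyme genes take most of the total, each comparison was repeated on values divided by median-of-ratios size factors (0.506 to 4.79). These were planned as an alternative for genes; their use for the lists, and as the default scale of the text, was chosen after the values were seen.

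Lists of genes (31, and a panel of 26 genes) were fixed before the data were examined, as were the tests on deposited values, the comparisons and the rule for naming genes; 30 lists had members measured. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, adjusted over lists and comparisons. At the preset correlation 135 of the tests passed as deposited and 164 after scaling. Arbitrary splits of the control libraries called a median of 11 of 30 lists as deposited. These calls were adjusted over the 30 lists alone, in a fit with 1 mean per genotype, so they are only a rough guide. A call at that correlation alone is weak. With an estimated correlation 8 passed as deposited and 0 after scaling; the 8 are the digestive enzymes after cerulein in KrasG12D pancreas at both days, between genotypes at day 7 and in the day 7 interaction, the acinar identity factors in the latter 2 and after cerulein in KrasG12D pancreas at day 7, and the gastric and tuft list between control genotypes. Named genes are the panel; per comparison the 6 largest increases and 6 largest decreases among genes past the threshold, without overlap between the groups (not asked of interactions) and with a mean in the upper 60 percent, leaving out predicted genes and immune receptor segments; up to 4 members with the smallest p per described list; and per mark and direction the 8 windows with the largest fold within 1 kb of a transcription start, and list members there. Elf3 and the lists named as written later were chosen after the values were seen.

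Regions were overlapped with bedtools 2.31.1, with at least 1 bp shared. Promoters were windows within 1 kb of the nearest start, or 3 kb as an alternative. Fisher's exact tests (two-sided) used SciPy 1.17.1, and lists were tested against genes with a differing promoter window of the same mark. Tags were recovered by dividing by each library's step; 100% of values came within 0.05 of a whole read. edgeR 4.0.16 (quasi-likelihood) on these reads called 26848 of 27357 H3K27ac windows (98.1%) and 4793 of 4944 H3K4me3 windows (96.9%) at an absolute log2 fold of at least 1, but is no independent check, as the windows had been chosen for differing. Coordinates are 1-based on mm10. Tables and figures used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Confidence intervals cover counting error only.

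The tests were checked on simulated data with 200 genes or windows changed. For cerulein in KrasG12D pancreas at day 3, limma over 10128 genes recovered 35.8% of genes changed by a log2 of 1, 89.6% at 2 and 98.5% at 3, with 11 unchanged genes called. For cerulein in WT pancreas at day 7 it recovered 50.7%, 92.5% and 97.0%, with 7 called. The changed genes were drawn from those with a mean log2 value above 3, and noise was independent between genes. The simulated values held no shift of the median gene and no effects shared within a library, and scaling by size factors was not simulated. These rates therefore do not describe the real comparisons, where such shifts are present. edgeR recovered 94.5% of windows changed by a log2 of 2 among 4944, with 10 false calls. The alternatives tried were other pseudocounts, filters, scalings, limma settings, library sets, thresholds, overlaps and promoter widths, and leaving out each library. Sequence motifs were not searched, as no genome was at hand.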

Results

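The deposited data comprised 35 samples from mouse pancreas and from a mouse pancreatic cancer cell line. RNA-seq of total pancreas gave 19 libraries in 8 groups. The mice carried Pdx1-Cre alone (WT) or Pdx1-Cre with the LSL-KrasG12D allele (KrasG12D), and were sampled as controls or 3 or 7 days after injection of cerulein, a secretagogue that causes acute pancreatitis. Controls comprised 2 WT and 3 KrasG12D libraries at day 3 and 2 of each genotype at day 7. Cerulein groups comprised 2 libraries of each genotype at day 3, and 4 WT and 2 KrasG12D libraries at day 7. The cell line, UN-KC-6141, comes from a KrasG12D pancreatic tumour. Its control and Ezh2-knockout (Ezh2KO) clones, 2 per genotype, were profiled by ATAC-seq (4 libraries) and by ChIP-seq for H3K27ac and H3K4me3 (4 libraries per mark), with 4 input libraries. EZH2 is the methyltransferase of Polycomb repressive complex 2 (PRC2).

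Digestive enzyme transcripts dominated the control pancreas. Transcripts of 32 digestive enzyme genes made up 81.1% ± 0.141 (SD, n = 2) of the summed values in WT controls at day 3 and 78.5% ± 4.93 (n = 2) at day 7. The share was 77.5% ± 3.32 (n = 3) and 77.4% ± 2.69 (n = 2) in KrasG12D controls. After cerulein it was 70.4% ± 8.61 (n = 2) in WT pancreas at day 3 and 78.1% ± 2.02 (n = 4) at day 7. In KrasG12D pancreas it was 31.9% ± 8.53 (n = 2) at day 3 and 24.1% ± 30.1 (n = 2) at day 7, the last from libraries at 45.4% and 2.77%. The first principal component held 88.9% of the variance and the next 2.92%. The values of a library summed to 545726 to 876337, and 2557 to 10902 genes reached a value of 5.

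**Figure D1:**
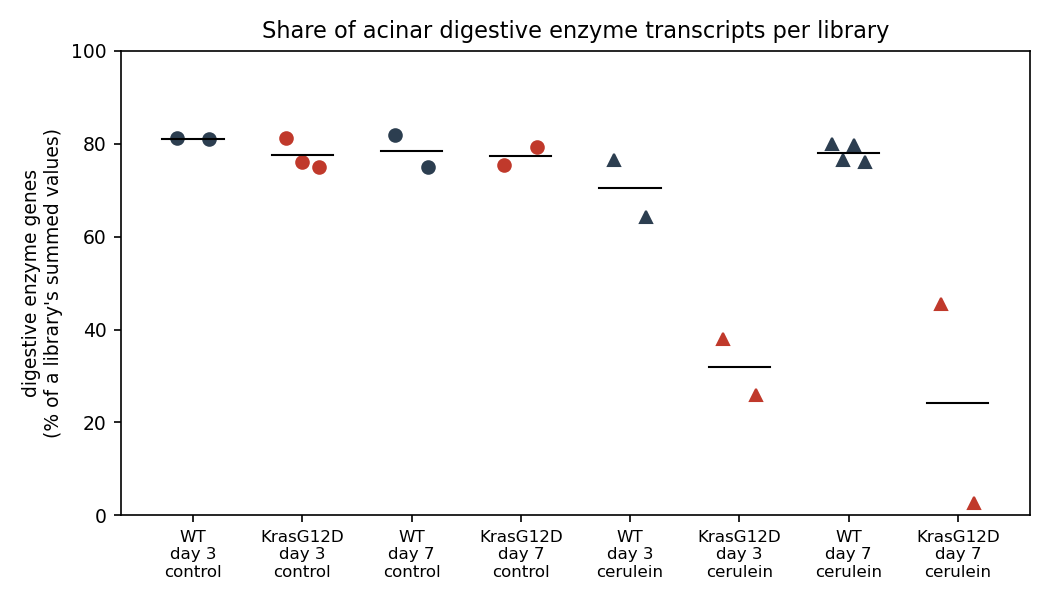
Percent of each library's summed expression values taken by acinar digestive enzyme genes, by group. Circles are controls, triangles cerulein libraries, dark blue WT, red KrasG12D, and lines group means. The 4 KrasG12D cerulein libraries lie between 2.77% and 45.4%, below each of the others.

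The deposited values also differed between groups as a whole. Cerulein in KrasG12D pancreas raised the median gene by 1.95 log2 units at day 3 and 2.11 at day 7, against 0.75 and 0.21 in WT pancreas. Between genotypes the median shift was 1.25 at day 3 and 1.82 at day 7 after cerulein, and −0.02 in controls. From day 3 to day 7 after cerulein it was −0.47 in WT and 0.06 in KrasG12D pancreas. Unless called deposited, fold changes below are log2 values ± SE after scaling by size factors, which set the median near 0. Counts of genes are given in both scalings.

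At 3 days after cerulein, the KrasG12D pancreas had lower acinar and higher duct transcripts than its controls. The question is how pancreatitis acts on a pancreas with the oncogene. The lipase Pnlip (−7.31 ± 1.03), the elastase Cela1 (−6.29 ± 0.95), chymotrypsin C (Ctrc, −6.09 ± 0.72), phospholipase Pla2g1b (−6.25 ± 0.85) and the cargo receptor Tmed11 (−5.31 ± 0.46) fell (adjusted p 2.38e-05 to 0.000262). Carboxypeptidase Cpa1 fell by 4.04 ± 1.07 (adjusted p = 0.00739), and the value of the acinar transcription factor Bhlha15 was −3.46 ± 0.81 (0.00414; 0.173 as deposited). The tight junction gene Cldn4 rose by 5.13 ± 0.56, lipocalin Lcn2 by 4.43 ± 0.86, the protease inhibitor Timp1 by 4.67 ± 0.73, cathepsin Ctse by 4.34 ± 0.72, gastrokine Gkn3 by 4.15 ± 1.02 and the membrane protein gene Itm2a by 4.03 ± 0.33 (adjusted p 1.45e-05 to 0.00555). The duct keratin Krt19 rose by 3.03 ± 0.69, the chloride channel Cftr by 2.46 ± 0.39 and the epithelial adhesion gene Epcam by 2.63 ± 0.43 (adjusted p 0.000343 to 0.00357).

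Macrophage, matrix and cell cycle genes were also higher at that time in KrasG12D pancreas. Macrophage genes Adgre1 (2.23 ± 0.47), Fcgr1 (2.33 ± 0.33) and Trem2 (2.90 ± 0.44) rose, as did collagen Col1a1 (2.91 ± 0.60), the matrix protease Mmp2 (2.46 ± 0.28) and the matrix glycoprotein Sparc (2.51 ± 0.35). The cell cycle genes Cdk1 (1.61 ± 0.26) and Ube2c (2.62 ± 0.47) rose too, and so did the cytokine antagonist Il1rn (3.34 ± 0.55) and the cytokine Lif (1.59 ± 0.31), with adjusted p of 7.03e-05 to 0.00208 over these 10 genes. Nfe2l2, which encodes NRF2, the oxidative stress regulator in the series title, rose by 1.28 ± 0.24 (adjusted p = 0.000945). Among oxidative stress genes, Hmox1 (1.87 ± 0.34), peroxiredoxin Prdx1 (1.50 ± 0.21), carbonyl reductase Cbr3 (1.55 ± 0.25) and thioredoxin reductase Txnrd1 (0.69 ± 0.15) rose (adjusted p 0.000178 to 0.00218). Ezh2 was higher by 0.67 ± 0.23 (adjusted p = 0.0258) and Kras by 0.73 ± 0.19 (0.00623). The direction depended on the scaling for the NRF2 inhibitor Keap1 (1.42 ± 0.29 deposited, −0.51 ± 0.19 scaled), its partner Sqstm1 (1.70 ± 0.27 and −0.60 ± 0.18), and the acinar regulators Xbp1 (1.17 ± 0.22 and −1.15 ± 0.26) and Nr5a2 (0.81 ± 0.24 and −1.30 ± 0.32).

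In this day 3 KrasG12D comparison limma called 9489 genes higher and 78 lower as deposited (99.2% higher), and 2272 higher and 2218 lower with size factors (50.6% higher). By list, 22 of 28 digestive enzymes were lower (24 when adjusted over the list alone), with a median of −4.19 (camera adjusted p = 1.7e-07), and 11 of 13 acinar identity factors (13 adjusted over the list alone; −3.11, 9.1e-05). Higher lists were fibroblast and matrix (27 of 30, median 2.21, adjusted p = 3.7e-10), proliferation (28 of 30, 1.40, 2.4e-09), ductal and metaplasia (17 of 22, 2.29, 1.2e-06), macrophage (20 of 23, 2.14, 3.4e-06), inflammatory cytokines (15 of 23, 1.06, 0.0032) and NRF2 targets (14 of 28, with 4 lower; 0.60, 0.043). Adjusted over the list alone these 6 counts were 27, 29, 17, 20, 15 and 14. With an estimated correlation the adjusted p of these 8 lists was 0.58 to 0.61 after scaling; the digestive enzyme call held in the deposited values (adjusted p = 0.023). As deposited, macrophage genes (adjusted p = 0.18) and inflammatory cytokines (0.0805, ranked below other genes) were not called at the preset correlation. Without KrasG12D cerulein library 12 the scaled count fell to 2261 genes, and Cpa1, Bhlha15, Nr5a2, Ezh2, Kras, Keap1 and Sqstm1 lost their calls. The calls of Keap1 (without control libraries 2 or 5), Sqstm1 (control 5) and Ezh2 (control 13 or cerulein 11) and the deposited call of Cpa1 (adjusted p = 0.0488; without any 1 of 17 of the 19 libraries) were also lost.

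**Figure D2:**
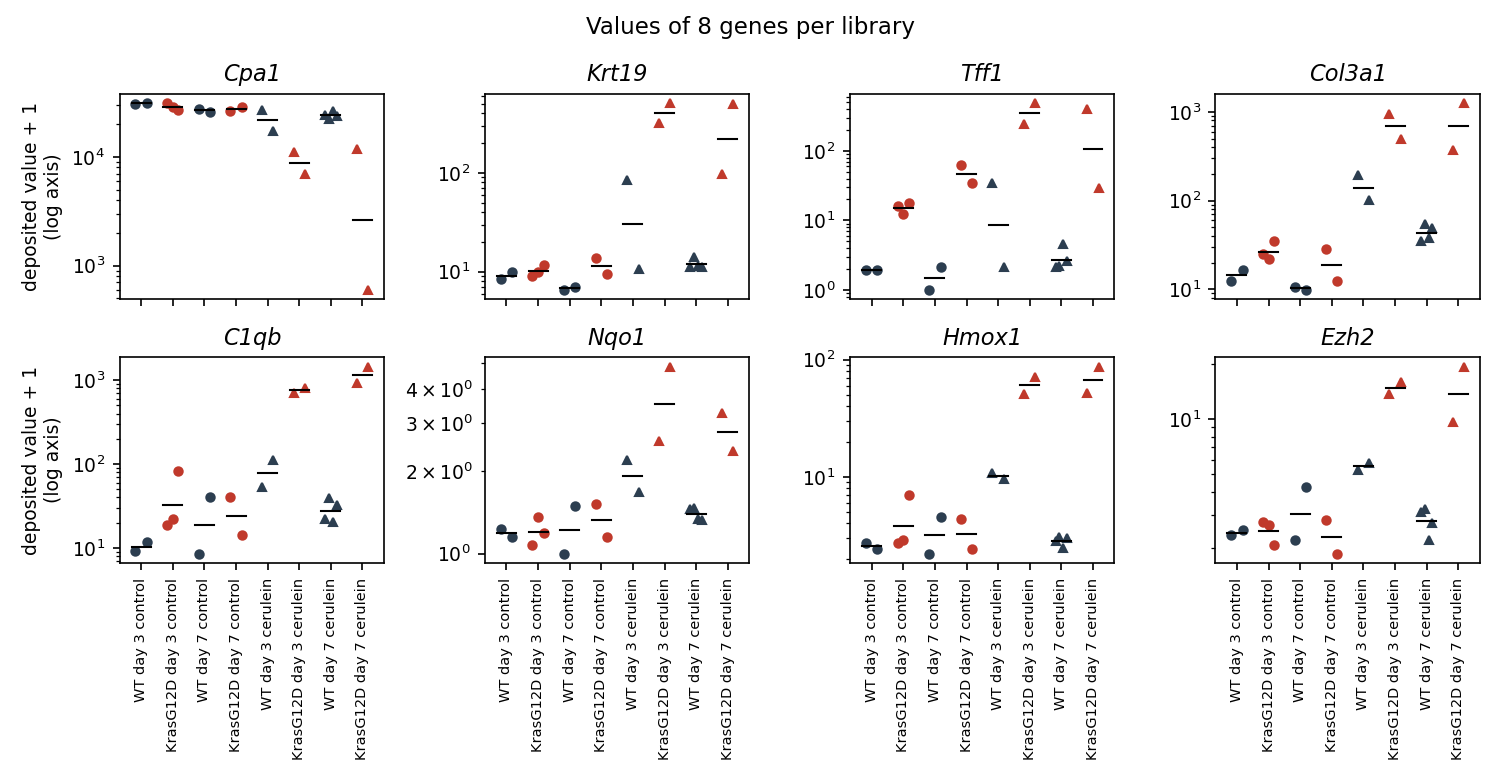
Deposited value plus 1 (log axis) of 8 genes in each of the 19 RNA libraries, by group; circles are controls, triangles cerulein libraries, and bars geometric means. The values are as deposited, so the shift of the median gene of 1.95 (day 3) and 2.11 (day 7) log2 units in KrasG12D pancreas is part of what is seen.

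By 7 days after cerulein, macrophage and matrix genes stood high and acinar genes low in KrasG12D pancreas. The chemokine Ccl6 rose by 3.89 ± 0.81, apolipoprotein Apoe by 3.50 ± 0.61, the lysosomal protease Ctss by 3.50 ± 0.81, the Fc receptors Fcgr3 and Fcgr1 by 3.57 ± 0.67 and 2.81 ± 0.36, Trem2 by 3.19 ± 0.49 and the chemokine receptor Cx3cr1 by 2.37 ± 0.41 (adjusted p 0.000199 to 0.00415). The proteases Mmp7 (4.17 ± 0.81) and Mmp2 (2.62 ± 0.31), the collagen crosslinker Loxl1 (2.38 ± 0.36) and the acute phase gene Saa3 (3.89 ± 1.25) rose (adjusted p 0.000152 to 0.0239). Antigen presentation genes H2-DMb1 (2.84 ± 0.64) and H2-Ab1 (2.80 ± 0.84), the interferon-induced genes Oasl2 (1.99 ± 0.33) and Ifit1 (1.44 ± 0.39) and the cytokines Il1b (2.47 ± 0.47) and Ccl3 (1.57 ± 0.25) also rose (adjusted p 0.000462 to 0.0174). The zymogen granule gene Sycn fell by 6.53 ± 1.07, Cela1 by 6.52 ± 1.04, Pnlip by 6.44 ± 1.13, Pla2g1b by 6.05 ± 0.94, Ctrc by 5.94 ± 0.79, Tmed11 by 5.52 ± 0.51 and the acinar master factor Ptf1a by 3.64 ± 0.72 (adjusted p 9.85e-05 to 0.00178).

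Nfe2l2 and Hmox1 were also higher at day 7 in KrasG12D pancreas. Nfe2l2 (1.53 ± 0.27, adjusted p = 0.000711), Hmox1 (2.13 ± 0.37, 0.000765), the stress factor Atf3 (1.71 ± 0.27, 0.000405) and Cdkn2a, which encodes p16 and p19ARF (2.27 ± 0.47, 0.00182), rose. Ezh2 passed only as deposited (2.58 ± 0.36, adjusted p = 2.3e-06; scaled 0.60 ± 0.25, 0.066). The glutathione synthesis gene Gclc (1.37 ± 0.32 deposited, −0.84 ± 0.26 scaled) and Xbp1 (0.86 ± 0.24 and −1.63 ± 0.29) again changed direction with the scaling.

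For day 7 in KrasG12D pancreas limma called 9560 genes higher and 119 lower as deposited (98.8% higher), and 2129 higher and 1922 lower with size factors (52.6%). Of the lists, 26 of 28 digestive enzymes were lower (27 adjusted over the list alone; median −5.76, camera adjusted p = 6.8e-11) and 13 of 13 acinar identity factors (−3.64, 4.5e-07). The endoplasmic reticulum stress list had 15 of 23 lower and 2 higher (median −1.44 scaled but 0.94 as deposited; 7.9e-05). Higher lists were fibroblast and matrix (26 of 30, 2.19, adjusted p = 1e-09), macrophage (19 of 23, 2.71, 1.7e-07), ductal and metaplasia (12 of 22, 1.42, 0.0011), interferon response (6 of 21, 1.14, 0.0015) and MHC class II (6 of 7, 2.84, 0.011), or 27, 20, 12, 5 and 6 adjusted over the list alone. NRF2 targets were not called (9 higher and 4 lower of 28; median 0.30, adjusted p = 0.16). With an estimated correlation the adjusted p of the 8 called lists was 0.58 to 0.65 after scaling, and the acinar lists held as deposited (0.022 each). At the preset correlation macrophage (adjusted p = 0.0883), ductal (0.221), interferon (0.53) and MHC class II genes (0.795) were not called as deposited. The scaled count fell to 1922 without control library 16 and 1959 without cerulein library 18. Single libraries ended the scaled calls of Saa3 (15, 16 or 18), Gclc (15 or 18), Ctss and H2-DMb1 (16), and H2-Ab1 and Ifit1 (16 or 17).

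**Figure D3:**
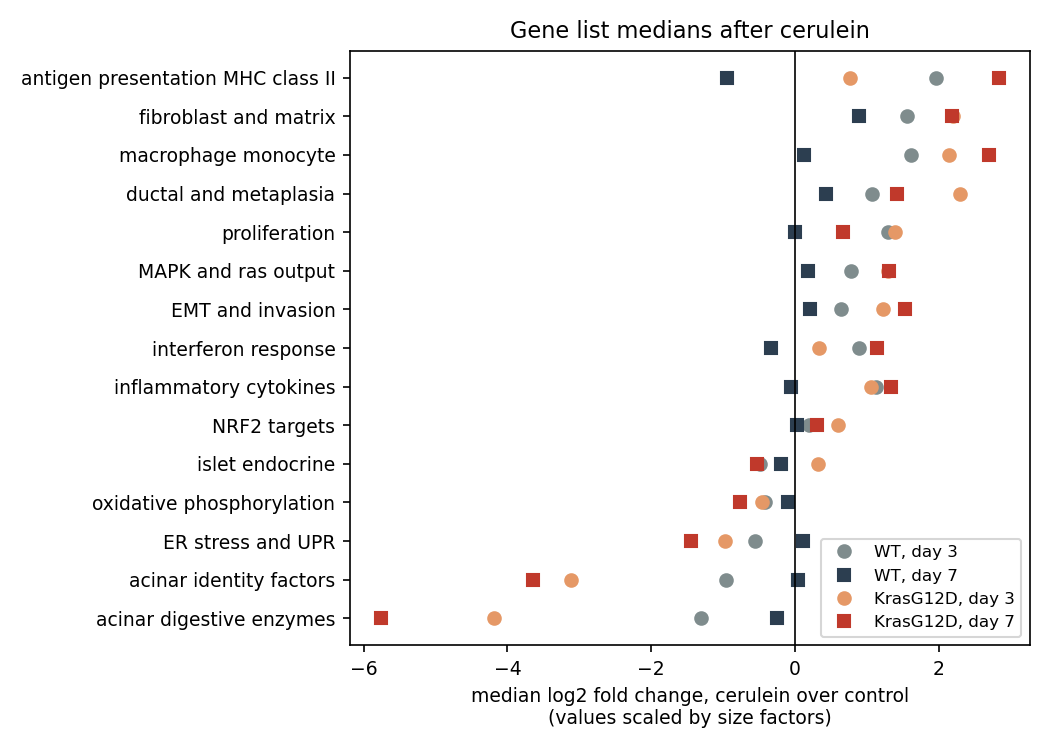
Median log2 fold change, after size factor scaling, of the measured members of 15 gene lists in the 4 comparisons of cerulein with control. Digestive enzymes have medians of −4.19 and −5.76 in KrasG12D pancreas at days 3 and 7, against −1.31 and −0.24 in WT pancreas.

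In WT pancreas cerulein raised matrix and cell cycle genes at day 3. Periostin (Postn, 3.12 ± 0.52), lumican (Lum, 2.38 ± 0.41), collagen Col3a1 (2.33 ± 0.47), Mmp2 (1.64 ± 0.31), Ube2c (2.72 ± 0.52), survivin (Birc5, 1.81 ± 0.35) and Mki67 (1.80 ± 0.37) passed in both scalings (scaled adjusted p 0.034 to 0.0479). Col1a1 (2.87 ± 0.66), Ctse (3.39 ± 0.79), Cd68 (2.36 ± 0.53), Mrc1 (1.98 ± 0.49), Trem2 (1.85 ± 0.49), Ctss (2.86 ± 0.81), Reg3g (3.01 ± 1.29), Arhgdib (3.18 ± 1.10) and Hmox1 (1.26 ± 0.37) passed only as deposited (scaled adjusted p 0.0582 to 0.16). So did Nfe2l2 (0.69 ± 0.27, 0.132 scaled) and Ezh2 (0.51 ± 0.25, 0.199). The counts were 3171 higher and 0 lower as deposited (5235 at an unadjusted p under 0.05 by limma) and 39 higher and 10 lower with size factors (79.6% higher). Fibroblast and matrix members (4 of 30 called, 27 adjusted over the list alone; median 1.56, camera adjusted p = 6.7e-15), proliferation members (6 of 30, 25 alone; 1.29, 1.9e-14) and macrophage members (0 of 23, 16 alone; 1.62, 1.3e-08) were called as lists with higher values. Digestive enzymes had a median of −1.31 (0 of 28 called, 0 adjusted over the list alone; adjusted p = 0.014). Cerulein library 3 held lymph node transcripts (Ccl21a at 122), and without the 3 libraries that did, the digestive enzyme list was not called (−0.86, adjusted p = 0.172). The 4 lists had, over all libraries and with an estimated correlation, an adjusted p of 0.58 to 0.81.

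Single libraries decided that WT day 3 count. As deposited it was 4 without control library 4 and 0 without control library 6, and none of the 18 genes named passed without either. It was 5976 without cerulein library 1 and 208 without library 3, 5637 without KrasG12D day 7 cerulein library 17 and 5441 without library 18. The 7 genes that passed in both scalings lost their scaled calls without WT control library 4 or 6, cerulein library 1 or day 7 cerulein library 9.

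At day 7 after cerulein no gene passed in WT pancreas. limma called 0 genes in either scaling, with 494 genes at an unadjusted p under 0.05 as deposited and 639 with size factors. The values were 1.83 ± 0.41 for Col3a1, 1.24 ± 0.31 for fibrillin Fbn1 and 1.05 ± 0.26 for Mmp2 (adjusted p 0.268 to 0.38). Fibroblast and matrix genes were called as a list (0 of 30 singly, 14 adjusted over the list alone; median 0.90, camera adjusted p = 1.2e-12; adjusted p = 0.58 with an estimated correlation). Lower medians came from T and NK cell genes (−1.57, adjusted p = 7.1e-07) and B cell genes (−1.77, 0.00063), with 0 members called in either count, among them Cd3g (−2.30 ± 1.02), Ccr7 (−2.12 ± 0.98) and Fcer2a (−1.77 ± 0.97). These 2 had, with an estimated correlation, adjusted p of 0.58 and 0.59. Lymph node transcripts were present in WT control library 14, where the chemokine Ccl21a read 55.6 against 0.402 in control library 7. Nfe2l2 (−0.02 ± 0.23), Hmox1 (−0.35 ± 0.32) and Ezh2 (−0.32 ± 0.22) did not pass (adjusted p 0.825 to 0.994). Left-out libraries gave at most 5 genes as deposited (without KrasG12D day 7 cerulein 17 or 18) and 14 scaled (without control 7; 1 without KrasG12D day 3 cerulein 11 or 12).

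Without cerulein, which asks for the oncogene's effect alone, no single gene passed between genotypes. limma called 0 genes, with 125 at an unadjusted p under 0.05 as deposited and 546 with size factors. Gastric genes of pancreatic intraepithelial neoplasia had values of 4.41 ± 0.87 (trefoil factor Tff1), 4.35 ± 0.78 (Gkn1), 4.03 ± 0.80 (Gkn2) and 2.81 ± 0.76 (Gkn3), with scaled adjusted p of 0.263 to 0.645. Reg3g (3.06 ± 0.87), Krt20 (1.90 ± 0.52), the monocyte receptor Ccr2 (1.25 ± 0.37) and the RAS output gene Etv5 (0.86 ± 0.18) had adjusted p of 0.3 to 0.645. The gastric and tuft list was called (0 of 13 members, 5 adjusted over the list alone; median 1.10, camera adjusted p = 1.3e-08). It was 0.58 with an estimated correlation after scaling, and 0.022 as deposited. Macrophage (median 0.55, 7.6e-08), fibroblast and matrix (0.44, 1.4e-08) and RAS output (0.35, 3e-07) lists were called with 0 members each (1 RAS output gene adjusted over the list alone), and had adjusted p of 0.58 with an estimated correlation. Arbitrary splits of the control libraries called a median of 11 of 30 lists as deposited, adjusted over these lists alone, so such calls are weak. The macrophage mean log2 value was 3.10 in KrasG12D day 3 control 13, against 1.63 and 1.74 in its group. It was 2.72 in WT day 7 control 14 and 2.56 in KrasG12D day 7 control 15, against 1.11 and 1.38 in the other day 7 controls. Kras (−0.00 ± 0.14), Ezh2 (−0.20 ± 0.17) and Nfe2l2 (−0.10 ± 0.18) had an adjusted p of 1. Leaving out libraries gave at most 4 genes as deposited (without KrasG12D day 7 cerulein 18; 3 without 17) and 6 scaled (without the same library 18; 5 without 17). Without KrasG12D day 3 control 2 (deposited) or WT day 3 cerulein 1 or 3 (both scalings) it was 1.

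The genotypes were then compared within cerulein groups, which asks what the oncogene adds to pancreatitis. At 3 days KrasG12D pancreas had higher epithelial and fewer acinar transcripts than WT pancreas. Cldn4 (4.01 ± 0.61), Phgr1 (3.24 ± 0.51), the serine protease Prss22 (2.97 ± 0.59), Cldn7 (2.14 ± 0.36), Epcam (2.09 ± 0.47) and Krt18 (1.13 ± 0.32) were higher (adjusted p 0.00443 to 0.0282). So were the endotoxin receptor Cd14 (2.57 ± 0.43), Trem2 (2.19 ± 0.49), the matrix proteases Mmp3 (2.04 ± 0.33) and Mmp14 (1.69 ± 0.32), the RAS output genes Etv5 (0.97 ± 0.26) and Dusp4 (1.30 ± 0.32), Prdx1 (1.32 ± 0.23) and the pentose phosphate gene Pgd (1.22 ± 0.23), with adjusted p of 0.0045 to 0.0247. Pnlip (−5.75 ± 1.13), Pla2g1b (−5.34 ± 0.94), Ctrc (−5.21 ± 0.79), Cela1 (−5.17 ± 1.04), the neuropeptide Gal (−5.16 ± 0.69) and Tmed11 (−4.40 ± 0.51) were lower (0.00103 to 0.00869). Tff1 (3.78 ± 1.29), Gkn3 (3.33 ± 1.12), S100a8 (3.69 ± 1.33), Hmox1 (1.15 ± 0.37, adjusted p = 0.0501), Nfe2l2 (0.55 ± 0.27), Kras (0.56 ± 0.21) and Ezh2 (0.13 ± 0.25, 0.754) passed only as deposited.

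The count for that day 3 genotype difference was 7965 higher and 104 lower as deposited (98.7% higher) and 688 higher and 824 lower scaled (45.5%). Ductal and metaplasia genes (10 of 22, 17 adjusted over the list alone; median 1.68, camera adjusted p = 2.8e-07), macrophage genes (5 of 23, 11 alone; 1.36, 3.6e-05), RAS output genes (8 of 21, 13 alone; 0.82, 2.7e-05) and NRF2 targets (7 of 28 with 2 lower, 9 and 3 alone; 0.46, 0.0069) were higher as lists. Digestive enzymes were lower (10 of 28, 20 alone; −3.10, 4.5e-08). With an estimated correlation the adjusted p of these 5 was 0.58 to 0.61, and as deposited macrophage genes were not called (0.153 at the preset correlation). Without KrasG12D cerulein library 12, 6 genes passed after scaling. Without WT cerulein library 1 the counts were 5162 as deposited and 881 scaled, with Trem2 and Etv5 lost, and without library 3, 944 scaled, with Krt18, Epcam, Etv5 and Dusp4 lost. Etv5 was also lost without KrasG12D cerulein library 11, and the deposited call of S100a8 without WT library 1 or KrasG12D library 12.

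At day 7 after cerulein KrasG12D pancreas had higher myeloid and lower acinar transcripts than WT pancreas. The eosinophil ribonucleases Ear3 and Ear12, near-identical copies whose reads cannot be told apart with certainty, were both higher by 4.59 ± 0.59, the lectin Clec4n by 4.30 ± 0.53, Ccl6 by 4.27 ± 0.70, Ctss by 4.22 ± 0.70, the chemokine Ccl8 by 4.19 ± 0.77, Ccr2 by 3.72 ± 0.47 and Fcgr1 by 3.08 ± 0.31 (adjusted p 1.84e-05 to 0.000618). H2-Ab1 (3.63 ± 0.73), H2-DMb1 (3.47 ± 0.55), Oas1a (2.43 ± 0.41), Oasl2 (1.78 ± 0.29), and the neutrophil genes Mmp9 (1.75 ± 0.29) and Csf3r (1.66 ± 0.24) were higher (0.000104 to 0.00115). The transcription factor Onecut2 (2.31 ± 0.35), Anxa10 (2.60 ± 0.51), Tff1 (3.43 ± 1.11), the RAS pathway genes Fos (2.28 ± 0.32) and Dusp6 (2.08 ± 0.33) and the glycolysis genes Pfkp (1.32 ± 0.22) and Pkm (0.92 ± 0.16) were higher (8.68e-05 to 0.0208). Cela1 (−6.53 ± 0.90), Tmed11 (−6.18 ± 0.44), Pla2g1b (−5.95 ± 0.81), Ctrc (−5.78 ± 0.69), Gal (−5.77 ± 0.59), Cela3a (−5.47 ± 0.74) and Ptf1a (−3.48 ± 0.62) were lower (5.22e-06 to 0.00054). Hmox1 (2.64 ± 0.32, 3.95e-05), Nfe2l2 (1.39 ± 0.23, 0.000253), Cdkn2a (1.94 ± 0.40, 0.00119), Ezh2 (0.55 ± 0.22, 0.046) and Kras (0.50 ± 0.18, 0.031) were higher.

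That day 7 difference comprised 9352 genes higher and 201 lower as deposited (97.9% higher) and 2679 higher and 2366 lower scaled (53.1%). As lists, macrophage genes (20 of 23, 21 adjusted over the list alone; median 2.72, camera adjusted p = 4.9e-08), MHC class II (7 of 7, 7 alone; 3.63, 0.0021), interferon response (16 of 21, 18 alone; 1.56, 6.5e-05), inflammatory cytokines (16 of 23, 16 alone; 1.36, 0.0026) and the gastric and tuft list (10 of 13, 10 alone; 2.31, 0.033) were higher. Digestive enzymes (28 of 28, 28 alone; −5.32, 3.7e-10) and acinar identity factors (13 of 13, 13 alone; −4.21, 1.2e-06) were lower. With an estimated correlation the adjusted p of these 7 was 0.58 to 0.61, and the acinar lists held as deposited (0.022 each). At the preset correlation MHC class II (adjusted p = 0.258), interferon (0.0629), inflammatory cytokine (0.328) and gastric and tuft genes (0.498) were not called as deposited, the last 2 ranked below other genes. The scaled count was 2806 without KrasG12D cerulein library 18. Ezh2 lost its scaled call without any 1 of 9 of the 19 libraries, Kras without WT cerulein library 8 or 10 or KrasG12D library 18, and Tff1 without library 17.

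Whether cerulein acted differently in the 2 genotypes was tested as an interaction. At day 7 the myeloid genes Ctss (3.91 ± 1.07), Adgre1 (2.52 ± 0.68) and Fcgr1 (2.48 ± 0.48), the actin-binding gene Cotl1 (3.82 ± 1.08), H2-Eb1 (3.78 ± 1.28), Hmox1 (2.48 ± 0.49), Cdkn2a (2.26 ± 0.62) and Nfe2l2 (1.55 ± 0.35) responded more in KrasG12D pancreas (adjusted p 0.00451 to 0.0447). Cela1 (−6.36 ± 1.38), Pla2g1b (−6.01 ± 1.24) and Tmed11 (−5.43 ± 0.67) had the opposite sign (0.00252 to 0.00656). Ezh2 (0.92 ± 0.33, 0.0516) and Kras (0.50 ± 0.27, 0.182) passed only as deposited. The day 7 interaction comprised 8935 positive and 116 negative genes as deposited (98.7% positive) and 1242 and 1329 scaled (48.3%). Macrophage genes (16 of 23, 19 adjusted over the list alone; median 2.52, camera adjusted p = 2.8e-07), MHC class II (5 of 7, 7 alone; 3.74, 0.0017) and digestive enzymes (24 of 28, 28 alone; −5.48, 3.7e-10) were called; with an estimated correlation the adjusted p was 0.58 to 0.6, and digestive enzymes held as deposited (0.024). MHC class II was not called as deposited (adjusted p = 0.215 at the preset correlation). The scaled count was 735 without WT control library 14, 610 without KrasG12D control 16 and 1022 without KrasG12D cerulein 18. Each of these ended the calls of Ctss, Cotl1 and H2-Eb1, libraries 14 and 16 also those of Adgre1 and Cdkn2a, and library 16 that of Nfe2l2. KrasG12D cerulein 17 ended that of Cotl1, and H2-Eb1 lost its call without any 1 of 13 of the 19 libraries.

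The day 3 interaction held in the deposited values but not after scaling. It comprised 5394 positive and 28 negative genes as deposited (99.5% positive), and 0 by limma with size factors (1441 at an unadjusted p under 0.05). The glutathione peroxidase Gpx2 (4.12 ± 0.45 deposited; 2.52 ± 0.37 scaled, adjusted p = 0.0512), Phgr1 (2.80 ± 0.70), Cldn4 (3.52 ± 0.83), Pnlip (−5.42 ± 1.52), Ctrc (−4.71 ± 1.07) and Tmed11 (−3.90 ± 0.69) had scaled adjusted p of 0.0512 to 0.182. Nfe2l2 (0.59 ± 0.36), Hmox1 (0.60 ± 0.50) and Ezh2 (0.16 ± 0.34) had 0.472 to 0.86. Digestive enzymes (0 of 28, 5 adjusted over the list alone; median −2.91, camera adjusted p = 6.1e-08) and ductal genes (0 of 22, 2 alone; 1.34, 2.3e-06) were called as lists, with adjusted p of 0.61 and 0.58 with an estimated correlation. The deposited count was 4 without KrasG12D cerulein library 12, 610 without WT cerulein library 1, 2157 and 1429 without WT control libraries 4 and 6, and 3483 without KrasG12D control library 2.

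From day 3 to day 7 after cerulein, few genes passed in WT pancreas. The cytokine Il33 (−2.87 ± 0.55), the lipase Pla2g7 (−2.41 ± 0.42), Glipr1 (−1.86 ± 0.39), Hmox1 (−1.85 ± 0.36), the sulfatase Sulf2 (−1.84 ± 0.40) and the Golgi gene Golm1 (−1.81 ± 0.39) were lower as deposited (adjusted p 0.0265 to 0.0481) and had scaled adjusted p of 0.0804 to 0.0924. Nfe2l2 (−0.92 ± 0.23 scaled, 0.088) and Ezh2 (−0.56 ± 0.22, 0.159) did not pass. The counts were 0 higher and 45 lower as deposited and 4 higher and 2 lower with size factors, with 3101 and 2314 at an unadjusted p under 0.05 by limma. Fibroblast and matrix (median −0.94, camera adjusted p = 7.2e-09; 9 of 30 adjusted over the list alone), macrophage (−1.003, 6.3e-07; 4 of 23) and proliferation genes (−0.71, 1.6e-07; 6 of 30) were lower as lists, with 0 members called over all genes and an adjusted p of 0.58 to 0.59 with an estimated correlation. Without any 1 of the 4 WT day 7 cerulein libraries none of the 6 genes passed, and 0 (libraries 8, 9 and 10) or 3 genes (19) were called as deposited. The count was 1314 without WT day 3 cerulein library 1, and 2255 and 2182 without KrasG12D day 7 cerulein libraries 17 and 18.

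In KrasG12D pancreas antigen presentation genes gave the largest list difference between day 7 and day 3. The MHC class II genes H2-Ab1 (2.24 ± 0.84) and H2-DMb1 (2.01 ± 0.64), the invariant chain Cd74 (2.40 ± 0.90) and their activator Ciita (1.88 ± 0.67) were higher in value (scaled adjusted p 0.735 to 0.828). The class II list was called (0 of 7, 5 adjusted over the list alone; median 2.19, camera adjusted p = 2.5e-07), as was the interferon list (0 of 21, 0 alone; 0.89, 3.2e-08), which includes Oasl2 (0.96 ± 0.33). As deposited, Ccr7 read 33.0 and 17.6 in day 7 libraries 17 and 18 against 7.97 and 7.59 at day 3, and Ccl21a 23.05 and 11.7 against 6.49 and 11.2. Lymph node transcripts did not rise as a set. The mean log2 value of a lymph node list, written after the values were seen, was 1.99 and 2.31 against 2.54 and 2.40 at day 3. The B cell gene Cd79a read 1.64 and 2.10 against 6.62 and 4.14. The class II and interferon lists each had a camera adjusted p of 0.58 with an estimated correlation. Ptf1a (−1.90 ± 0.72, adjusted p = 0.83), Nfe2l2 (−0.08 ± 0.27) and Ezh2 (−0.15 ± 0.25) did not pass. limma called 1 gene as deposited, the tetraspanin Tspan1 (−2.16 ± 0.35, adjusted p = 0.0404), and 0 after scaling (577 at an unadjusted p under 0.05). Tspan1 lost its call, leaving 0 genes, without any of 8 libraries (WT day 3 controls 4 and 6, KrasG12D day 3 controls 2 and 5, KrasG12D day 3 cerulein 12, WT day 7 cerulein 8, 10 and 19). Without KrasG12D day 7 cerulein 17 or 18, 616 or 133 genes passed.

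In the cell line, the edited gene came first. The window at the Ezh2 promoter (mm10 chromosome 6, 47594678 to 47595678) had lower H3K27ac in Ezh2KO clones: the deposited tags were 289.7 and 259.9 in the control clones and 105.2 and 61.42 in the knockout clones (authors' log2 −1.88, adjusted p = 0.000341). This reads neither EZH2 protein nor H3K27me3, and RNA of these clones was not analysed here. The comparison asks where active chromatin differs once EZH2 is removed.

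The transcription factors Hnf4a and Hnf1a had lower promoter marks in Ezh2KO clones. The Hnf4a promoter (chromosome 2, 163506316 to 163507316) had 298.3 and 253.6 H3K27ac tags in control clones and was listed at 0 in both knockout clones, and for H3K4me3 1044 and 1239 against 0. The Hnf1a promoter (chromosome 5, 114970619 to 114971619) had 302.0 and 239.3 H3K27ac tags against 0 and 1.18, and 844.9 and 857.5 for H3K4me3 against 0. E-cadherin (Cdh1, chromosome 8, 106602896 to 106603896) was lower in H3K27ac (log2 −4.59, adjusted p = 4.9e-07) and H3K4me3 (−2.36, 0.0149), as were Elf3 (−3.06 and −3.99), Foxa2 (−2.43 and −3.34), Krt19 (−2.52 and −1.63) and the alarmin Il33 (−2.72 and −2.65). H3K27ac was lower at Hnf1b (−2.08), Krt8 (−2.16), Gata6 (−1.47) and Pdx1 (−1.91), while Foxa1 had higher H3K4me3 (1.01, adjusted p = 0.0194). The promoter of the widely expressed gene Gapdh also had lower H3K27ac (−2.22). Where a promoter held several windows, 1 fold is given per mark, and the marks need not share a window. For Foxa2 the H3K27ac folds ran from −3.10 to −2.13 over its windows.

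Some genes of mesenchymal cells gained marks in the same Ezh2KO clones. H3K27ac was higher at the promoter of the matricellular gene Wisp1 (chromosome 15, 66891844 to 66892844, listed at 0 in both control clones, 150.9 and 244.5 tags in knockout clones). It was also higher at the growth factor receptor Pdgfrb, tenascin Tnc (log2 5.97), Timp1 (4.77), collagen Col5a1 (5.95 to 7.49 over its windows), fibronectin Fn1 (1.46) and the transcription factors Snai2 (2.77, authors' adjusted p = 1.34e-05) and Twist1 (2.77, 0.00128). The PRC2 target Hoxb9 (chromosome 11, 96270688 to 96271688) was listed at 0 for both marks in the control clones, with 106.9 and 114.6 H3K27ac and 442.9 and 400.8 H3K4me3 tags in knockout clones. The developmental genes Lhx2 (6.87), Dlx6 (7.57) and Gata3 (1.62) and Sulf2 (638.2 and 731.2 tags) and Bcat1 (636.2 and 627.0), both listed at 0 in control clones, had higher H3K4me3. Cytokine promoters Ccl2 (4.05), Il11 (4.38) and Lif (3.69) and the interferon gene Isg15 (3.21) had higher H3K27ac.

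NRF2-related promoters went both ways in Ezh2KO clones. Nqo1 (chromosome 8, 107403064 to 107404064) gained H3K27ac (4.95 and 1.79 tags in control, 37.53 and 22.44 in knockout clones; log2 3.03, adjusted p = 0.0405). Gclm (−2.12), Gsr (−1.55), Cbr3 (−2.06), Fth1 (−1.74) and the Nfe2l2 promoter (chromosome 2, 75704874 to 75705874; −1.35, 0.00386) had lower H3K27ac, while 5 windows at −58880, −52904, 17077, 18966 and 21598 bp from the Nfe2l2 start had higher H3K27ac (2.54 to 6.67). H3K4me3 was higher at the cystine transporter Slc7a11 (2.85) and thioredoxin Txn1 (1.18) and lower at Gsta1 (−4.59) and Tkt (−2.26), with 3 promoters of the list higher and 2 lower (adjusted p = 1, Fisher's exact test). Among NRF2 target promoters with a differing H3K27ac window, 1 was higher and 7 lower (adjusted p = 1, Fisher's exact test, two-sided). Over all genes with such a promoter, 818 were higher and 2407 lower. The widely expressed gene Gapdh (−1.45 and −2.22) and ribosomal protein genes (0 higher and 4 lower, such as Rpl19 at −1.35 and Rpl7 at −1.38) fell by similar amounts. Whether the losses at NRF2-related promoters go beyond this wider loss was not tested.

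**Figure D4:**
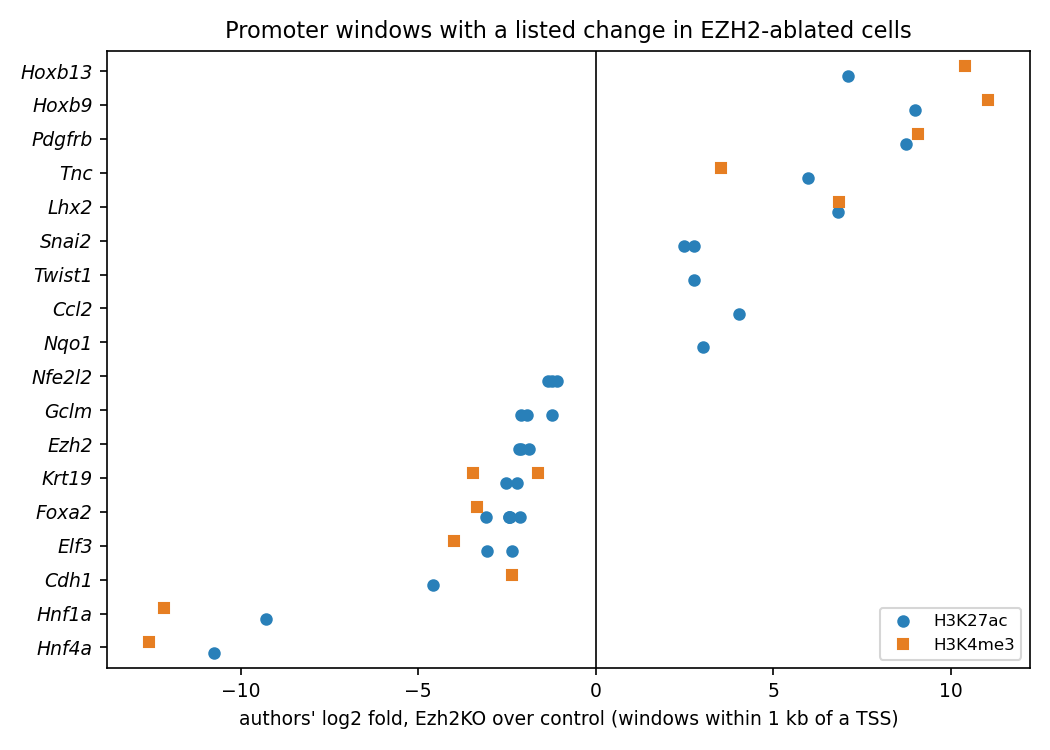
Authors' log2 fold (Ezh2KO over control) of windows within 1 kb of the start of 18 genes, circles for H3K27ac and squares for H3K4me3. Cdh1 has −4.59 and −2.36, and Tnc 5.97 and 3.53; folds of genes listed at 0 in 1 genotype depend on the authors' floor.

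The authors' tables listed 27357 H3K27ac windows that differed, 18153 higher in Ezh2KO clones (median log2 4.52) and 9204 lower (−1.97). Higher windows held a median of only 1 and 2 reads in the control clones, so their folds depend on the authors' floor. Lower windows kept a median of 57 and 36 reads in the knockout clones. The 2 medians therefore cannot be compared in size. Higher windows lay a median 26.9 kb from a transcription start and 6.05% within 1 kb, against 4.14 kb and 38.0% for lower windows. For H3K4me3, 4944 windows were listed, 3069 higher (median 2.84) and 1875 lower (−3.10). Scaling by total tags instead would shift the Ezh2KO folds by −0.48 for H3K27ac and 0.16 for H3K4me3. Of 3150 H3K4me3 windows that met an H3K27ac window, 3110 (98.7%) had the same direction, with 1749 higher and 1361 lower in both (odds ratio 7084, Fisher's exact test; windows are not independent). ATAC-seq listed 61638 regions in control and 55525 in Ezh2KO clones. Of these, 57.9% (95% exact binomial interval 57.5 to 58.3) and 64.2% (63.8 to 64.6) overlapped the other set. A change in the degree of accessibility was not measured. Instead, 16806 H3K27ac windows overlapped regions listed in only 1 genotype. Of these, 13855 (82.4%, odds ratio 24.5) had more H3K27ac in that genotype. The other listed H3K27ac windows were not counted, among them 514 that met such regions of both genotypes. Each set pools both clones, so accessibility has no replicate check.

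By gene list, fibroblast and matrix promoters leaned to higher H3K27ac in Ezh2KO clones, with 8 higher (Col1a1, Col5a1, Col6a1, Fbn1, Fn1, Pdgfrb, Timp1 and Tnc) and 1 lower (Vim). Their odds ratio was 23.8 (adjusted p = 0.00362, Fisher's exact test, two-sided), against 818 genes higher and 2407 lower overall. The same list had 8 higher and 0 lower for H3K4me3 (unadjusted p = 0.114, adjusted p = 1, Fisher's exact test). As most genes with a differing H3K4me3 promoter were higher, 8 of 8 could not pass. Other lists fixed in advance did not pass for H3K27ac, with 4 higher and 5 lower for epithelial to mesenchymal transition and invasion and 1 higher and 7 lower for ductal genes (adjusted p = 1 for each). With most genes lower for this mark, a short list of lower ductal genes does not stand out. PRC2 developmental targets had 6 higher, among them Hoxa10, Hoxb13 and Lhx2, and 5 lower, among them Cdx2, Foxa2 and Gata6 (adjusted p = 0.283). For H3K4me3 they had 13 higher and 1 lower (adjusted p = 1), where 1085 genes were higher and 438 lower overall. Inflammatory cytokines and interferon genes each had 4 higher and 1 lower (adjusted p = 0.17).

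Genes that gained promoter H3K27ac in Ezh2KO clones were called as a list in each of the 11 RNA comparisons once scaled, and in 0 of them with an estimated correlation (adjusted p 0.15 to 0.399). The list was higher in each except from day 3 to day 7 in WT pancreas (median −0.20). Of 367 such genes measured in the pancreas, 183 were higher and 38 lower at day 7 after cerulein in KrasG12D pancreas (194 and 40 adjusted over the list alone; median 0.85, camera adjusted p = 2.6e-07), and 171 higher and 55 lower at day 3 (181 and 58 alone; 0.65, 1.6e-05). In WT pancreas the medians were 0.40 at day 3 (adjusted p = 1.7e-05) and 0.085 at day 7 (0.0237). As deposited the adjusted p in KrasG12D pancreas at days 7 and 3 were 0.513 and 0.863, and the KrasG12D control difference alone passed (0.0455; 0.993 with an estimated correlation). The 1950 genes with lower promoter H3K27ac were called in 0 of the comparisons, with scaled adjusted p of 0.734 at day 7 and 0.559 at day 3. These windows come from a tumour cell line, and the RNA from whole tissue. Fibroblast and matrix genes and macrophage genes were also higher as lists, once scaled, after cerulein in KrasG12D pancreas. Of the fibroblast and matrix genes, 8 had gained promoter H3K27ac. Whether cell types account for the rise of the promoter list was not tested.

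The direction of the marks in Ezh2KO clones varied by chromosome. On chromosome 4, 86.7% of H3K27ac windows (1186 higher, 182 lower) and 92.5% of H3K4me3 windows were higher, against 66.4% and 62.1% genome-wide, and all 14 of its 10 Mb stretches lay above the genome-wide H3K27ac share. Chromosome X had 91.2% and 92.6%, and chromosome 19 41.4% and 34.1%. ATAC-seq regions numbered 1.36 times as many in Ezh2KO as in control clones on chromosome 4, 1.74 on X and 0.612 on 19, against 0.901 genome-wide. Tnc lies on chromosome 4, Timp1 on X and Il33 on 19, and each moved in the direction of most windows of its chromosome.

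**Figure D5:**
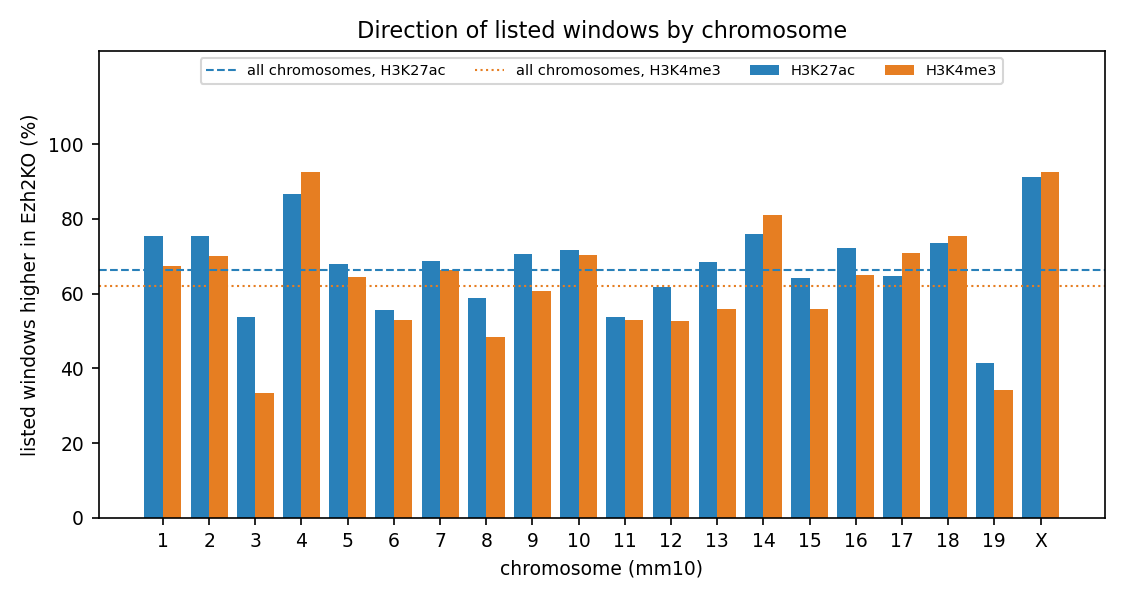
Percent of listed windows that are higher in Ezh2KO clones on each chromosome, for H3K27ac and H3K4me3. Horizontal lines give the genome-wide 66.4% and 62.1%; chromosomes 4 and X stand above them for both marks and 19 below.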

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

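All tests of explanations here were chosen after the results were seen. The genotype by cerulein interaction stood out because the effect of cerulein differed between genotypes by a test of the difference itself. It held for 5422 genes at day 3 as deposited and 0 with size factors, and for 9051 and 2571 at day 7. At day 7 the deposited log2 interactions were 6.12 for Ctss, 5.96 for Cotl1, 5.98 for H2-Eb1, 4.58 for Adgre1, 4.54 for Fcgr1, 4.53 for Hmox1, 3.80 for Cdkn2a and 3.65 for Nfe2l2, and −4.14 for Cela1, −3.86 for Pla2g1b and −3.84 for Tmed11. These 11 of the 13 named genes called as deposited are listed because they kept their sign and passed after scaling. Ezh2 and Kras passed only as deposited.

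Behind this lies a pattern in KrasG12D pancreas, where nearly all genes were higher after cerulein, by a median of 1.95 at day 3 and 2.11 at day 7. A smaller share of digestive enzyme transcripts may account for part of it: with these enzymes left out of the total the median was 0.92 at day 3 and 1.07 at day 7, which argues against them as the whole cause. Leaving out the 50 most abundant transcripts of the WT controls brought the medians to 0.10 and 0.098, so the loss of abundant transcripts can produce the shift by construction of a value relative to a total. Fewer acinar cells with every other cell type in its earlier proportion would raise markers of each type alike. Macrophage markers instead exceeded islet markers by 2.33 more in the 4 cerulein than in the 5 control libraries (p = 0.0159, exact permutation test, two-sided; lowest cerulein library 0.517, highest control −0.0846). Recruitment of macrophages and loss of enzyme expression within acinar cells stay open, as neither was tested.

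In the group of 4 WT day 7 cerulein libraries, 4 of 124 groups of values had 1 library apart from the other 3. These were Krt19 in library 9 (13.01 against 10.1 to 10.3), Oasl2 in library 19 (2.13 against 1.20 to 1.36), Mmp14 in library 19 (6.65 against 4.59 to 4.71) and Tspan1 in library 10 (0.85 against 1.27 to 1.35). Chance gives about 1 in 20 such groups, more than were found, and no explanation was tested.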

How the results depend on the processing

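Chosen after seeing the data were the fits without the 3 controls that stand apart or the 3 libraries with lymph node transcripts, all refits relative to size factors, the size factor runs of the lists and promoters, list tests with a library left out, the 3 kb promoters with size factors, and the edgeR fits other than the clone block. The others were planned. Of the values of single genes under a changed setting, 2541 kept their direction and side of the threshold, 155 lost their call, 27 gained one and 15 reversed. Reversed means a changed sign with a call before or after the change. With 1 library left out, 3841 kept both, 158 lost and 21 gained the call, and 0 reversed. Of the RNA counts under a changed setting 100 stayed within 1.5 times and 77 moved, and of the cell line values 12 stayed and 7 moved; where no construction is named, the cause was not tested. Numbers below are genes called, higher and lower together.

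Size factors remove the shift of the median by construction. They gave 49 genes for cerulein in WT at day 3, 4490 and 4051 for cerulein in KrasG12D at days 3 and 7, 1512 and 5045 between cerulein genotypes at days 3 and 7, 6 and 0 for day 7 against day 3 in WT and KrasG12D, and 0 and 2571 for the day 3 and day 7 interactions, with 11 calls for promoters in RNA. Reversed after size factors were Xbp1 (−1.15), Nr5a2 (−1.30), Keap1 (−0.51) and Sqstm1 (−0.60) at day 3 and Xbp1 (−1.63) and Gclc (−0.84) at day 7, each for cerulein in KrasG12D. Quantile normalization reversed Xbp1 (−0.91), Nr5a2 (−1.20), Keap1 (−0.51) and Sqstm1 (−0.39, which did not pass, limma adjusted p = 0.094) at day 3 and Xbp1 (−1.18) and Gclc (−0.87) at day 7. It gave 12 genes for WT at day 3, 4399 and 4087 for KrasG12D, 2143 and 5173 between cerulein genotypes, 10 for day 7 against day 3 in KrasG12D, and 30 and 2941 for the interactions. With digestive enzymes left out of the total, Xbp1 (−0.054) and Nr5a2 (−0.32) at day 3 and Xbp1 (−0.37) at day 7 changed sign but did not pass (limma adjusted p 0.13 to 0.81). The counts were then 987 for WT at day 3, 2846 between cerulein genotypes at day 3, 6 and 0 for day 7 against day 3 in WT and KrasG12D, and 481 and 5554 for the interactions.

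A pseudocount of 0.25 gave 7 and 0 genes for day 7 against day 3 in WT and KrasG12D, and 5 gave 3 and 133, and 395 for WT at day 3. With no filter on low values the counts were 1762 for WT at day 3, 15053 for KrasG12D at day 7, 1 between control genotypes, 15108 between cerulein genotypes at day 7, and 3 and 293 for day 7 against day 3. A minimum of 20 left fewer genes to test: 1993 for WT at day 3, 4149 and 4166 for KrasG12D, 3835 and 4130 between cerulein genotypes, 71 and 0 for day 7 against day 3, and 2876 and 3954 for the interactions. limma without trend and robust gave 22 and 2 for day 7 against day 3. Fitting only the groups compared gave 1114 and 14 for WT at days 3 and 7, 9 between control genotypes, and 2278 and 11 for day 7 against day 3. Array weights gave 1740 for WT at day 3, 4 between control genotypes, and 0 and 0 for day 7 against day 3. Day 7 against day 3 gave 1259 and 15 without the 3 controls that stand apart (KrasG12D day 3 control 13, WT day 7 control 14, KrasG12D day 7 control 15). Relative to size factors that set gave 1269 for WT at day 3, 891 for day 7 against day 3 in WT, and 6 and 1557 for the interactions. Without the 3 lymph node libraries there were 627 for WT at day 3, and 108 and 64 for day 7 against day 3. Relative to size factors that set gave 1032 and 1 for WT at days 3 and 7, 3 between control genotypes, 768 and 7 for day 7 against day 3, and 5 and 1620 for the interactions. An estimated correlation left 8 list tests and 0 promoter tests, and with size factors 0 and 0. A promoter width of 3 kb left 0 promoter tests as deposited and 10 with size factors.

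With single libraries left out the deposited counts ran from 0 to 5976 for WT at day 3, 0 to 5 for WT at day 7, 0 to 4 between control genotypes, 5162 to 8444 between cerulein genotypes at day 3, 0 to 2255 and 0 to 616 for day 7 against day 3 in WT and KrasG12D, and 4 to 6856 for the day 3 interaction. After size factors they ran from 0 to 707 and 0 to 14 for WT, 2261 to 4682 and 1922 to 4339 for KrasG12D at days 3 and 7, 0 to 6 between control genotypes, 6 to 1822 and 2806 to 5186 between cerulein genotypes, 0 to 532 and 0 to 104 for day 7 against day 3, and 0 to 250 and 610 to 3477 for the interactions. Where 1 library remains in a group, it is assumed to vary like the others. With few libraries per group, a call that 1 library ends says little about size.

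For the cell line, requiring an overlap of at least 50 percent of both regions gave 54.9% of control and 60.9% of Ezh2KO regions shared, and the stricter part of each set by score 49.7% and 68.5%. The score is saturated, so for control that part is all 38359 regions at the top score of 1000, and it is not equal in share between the sets. An adjusted p of at most 0.001 left 11405 H3K27ac and 2725 H3K4me3 windows. The 2 marks agreed in direction in 99.2% of windows when at least 50 percent of the H3K4me3 window had to overlap. edgeR called 3144 to 4160 H3K4me3 windows with 1 library left out. With the clone number as a replicate block edgeR called 25777 H3K27ac and 4646 H3K4me3 windows; the clones share only a number (correlation of their deviations −0.038 and −0.039, from 2 pairs). No paired analysis of the RNA was possible because no library numbers are shared between groups. DESeq2 was not run on the RNA table because it does not hold counts.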

Other observations

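All tests of explanations in this part were chosen after the results were seen. Ezh2KO clones may have shifted from an epithelial to a mesenchymal state. The test was the fibroblast and matrix list, fixed in advance, among genes with a differing H3K27ac promoter, with 8 higher and 1 lower (adjusted p = 0.00362, Fisher's exact test). For H3K27ac the list of epithelial to mesenchymal transition and invasion did not pass (4 higher and 5 lower, adjusted p = 1). Its lower genes were Cdh1, an epithelial gene, and Itgb1, Mmp14, Plaur and Vim. The shift therefore stays open. Neither the first list for H3K4me3 (8 higher and 0 lower) nor the ductal list for H3K27ac (1 higher and 7 lower) passed (adjusted p = 1 for each). All these lists were fixed in advance. The latter 2 tests cannot decide. With 1085 genes higher and 438 lower for H3K4me3, even 8 of 8 had an unadjusted p of 0.114 (Fisher's exact test). With 818 higher and 2407 lower for H3K27ac, mostly lower ductal genes do not stand out. Lower ductal genes such as Krt8, Krt18 and Krt19 are also what a shift would give. Whether such a shift would follow from the loss of EZH2 or from the choice of clones cannot be separated with 2 clones per genotype.

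Chromosome 4 had more windows with higher marks in Ezh2KO clones than the genome as a whole. A doubling of chromosome 4 in these clones may account for part of this. With a doubling taken off, 82.1% of its 179 H3K4me3 windows of an absolute log2 fold of at least 2 were higher (95% Wilson interval 75.9 to 87.0, and 88.3% before), against 59.0% in the rest of the genome. This cannot decide whether a doubling is the whole cause. Lower windows counted on chromosome 4 had smaller folds before the doubling was taken off, and small folds pass the authors' threshold less often. Windows that did not pass are missing, which may raise its share. For H3K27ac the shares were 83.5% and 78.4%. A doubling, gains of more than a doubling and real changes of chromatin stay open.

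WT day 7 control library 14, KrasG12D day 7 control library 15 and WT day 3 cerulein library 3 held lymph node transcripts. Ccl21a read 55.6, 17.6 and 122 in them, and the B cell gene Cd79a 18.3, 9.20 and 24.8, while KrasG12D day 7 cerulein library 17 had Ccl21a at 23.05 and the highest Ccr7 of the 19 libraries (33.0) but Cd79a at 1.64. Lymph node tissue taken along with the pancreas may be the source: of 16 other members of a list written after these values were seen, 15 (93.8%) were higher in each of the 3 than in the 12 other WT or control libraries. A lower acinar share would raise each other cell type alike, but in 3 of the 3 the lymph node mean stood higher against the fibroblast mean (by 0.13 to 1.76) and the islet mean (−1.002 to 0.32) than in the 16 other libraries (−4.95 to −1.31 and −3.75 to −1.99), which argues against it. That mean includes Ccl21a, Cd79a and the other genes by which the 3 were picked, so part of the excess was fixed in advance. Without these libraries the T cell list median for cerulein in WT at day 7 was −0.13 and the B cell list median 0.30 with size factors (3 and 4 genes kept), in place of −1.57 and −1.77 (11 and 7 genes).

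For the control genotypes, 100 of the 126 splits of the 9 control libraries were drawn, the real one included, and fitted on deposited values with 1 mean per genotype over both days. The real count of genes was 0, which all 100 splits reach by necessity, so this count says nothing about chance. Of the other splits 7 called any gene, the highest 143, which points to a structure among the control libraries, and what that split separates was not tested. For the number of lists called, 33 splits gave at least the real 13 (highest other 19, median of the others 11), so chance is not excluded. At the preset correlation, list calls were thus common in splits that do not follow genotype. For the gastric and tuft list, 2 of the 100 splits, the real one included, gave a p as small, which is under 0.05 for that list alone; 1 other split gave a smaller p, and 30 lists were tested.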
